A study of Mus musculus with 9 samples.

How the data were processed

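RNA sequencing was analysed for heart tissue of C57BL/6 mice, 4 vehicle samples and 5 samples given oxaliplatin at 10 mg/kg. Hearts were collected after 8 weeks and RNA of integrity above 8 was sequenced, per the series' design text. Libraries were made with a SMARTer kit, per the labels. Groups were taken from the titles. The labels give separate samples and say nothing more of how they relate, so p-values measure the spread between these samples, which may be technical.

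The deposited table holds a signal per gene and sample, named as normalized counts per the file headers, for 13795 gene symbols. STAR 2.5.1a, Partek and DESeq2 are named, without role or order, in the submitters' processing notes, and the design text credits Partek with the authors' own comparison. The genome build, annotation and strand setting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be told apart. Median-of-ratios factors computed from the deposited signal were equal over the samples, as they are once such factors have been divided out. Each gene reached at least 40.6 in some sample, so the deposited genes lack low ones. Totals of the deposited signal ran from 29.4 M to 36.9 M normalized counts per sample. Low values lay on steps of a fixed size per sample, and division by the step gave an estimated 28.5 M to 36.2 M reads. Of values between 1 and 1000 estimated reads, 73.0% to 75.9% per sample lay within 0.02 of a whole read. Whole reads were therefore not recovered, and a log-scale test was used in place of a count test.

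Groups were compared with limma 3.58.1 in R 4.3.3, with trend and robust moderation, on log2(normalized count + 1), for 13788 genes with a mean of at least 10 over all samples. Fold changes are on this scale, which understates the change of low genes. Tests were two-sided, and a Benjamini-Hochberg adjusted p under 0.05 passed. Of 52 gene lists, 30 for pathways and 22 for cell types and sex, the 47 with at least 5 measured members were tested together. Camera in limma set each list against all other genes, with a preset correlation of 0.01 and with an estimated correlation, and fry tested whether the genes of a list moved on balance in one direction. Each count of list members that passed over all genes is followed by the count adjusted over the list alone. A list score is the mean over its genes of log2(normalized count + 1), each gene centred on its mean over all samples.

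Genes were named by a rule. It took the 10 largest rises and 10 largest falls among genes that passed with groups that did not overlap, without predicted gene models and antigen receptor segments, and up to 4 members of smallest p per list that passed, or 2 where none did. Cdkn1a, Pdk4, Ppargc1a, Nppa, Nppb, Myh7, Mt1, Mt2 and Fgf21 were added to it, and Fgf21 was not analysed here. Of the genes the rule gave, those printed as examples were picked after their values were seen, and some genes of the rule are not reported here. Groups, tests, lists and rule were chosen before the data were examined, as were the alternatives of pseudocount, filter, scaling, limma settings, threshold, list test, replicate number as a block, removal of abundant gene classes, and leaving out each sample. Atrial and erythroid marker scores as covariates, removal of the 3 samples whose atrial score lay more than 1 above the mean of all samples, and voom on estimated reads were chosen after seeing the data. Those 3 samples were vehicle 1, oxaliplatin 2 and oxaliplatin 4, and the fit without them has less power to call genes. Coordinates are those of GENCODE M21 on GRCm38, matched by symbol, where 13589 of the symbols were found.

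The steps were tested on simulated data, in 8 tables of 13788 genes for oxaliplatin against vehicle with 200 genes changed in each. Of genes changed 1.5-fold 28% were recovered, 67.2% at 2-fold, 91% at 4-fold and 93.8% at 8-fold, and 71 of 1191 calls were false (5.96%). Each table held fewer changed genes than the 1966 that passed in the data. An adjusted p under 0.05 therefore asked for a smaller unadjusted p there, and recovery may be understated for these data. Camera called 40 of 40 raised lists and 1 of 320 unchanged lists of 25 independent genes. In the lists tested here the estimated correlation ran from -0.027 for metal handling to 0.915 for mitochondrially encoded genes, against the preset 0.01. It was 0.908 for complex I. The simulation therefore does not give the rate of false calls by camera for lists of correlated genes.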

Results

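Gene expression was measured by RNA sequencing in heart tissue of C57BL/6 mice, in 4 vehicle samples and 5 samples given oxaliplatin, a platinum drug used against cancer. An estimated 28.5 M to 36.2 M reads lay behind each sample, and mitochondrially encoded genes took 18.1% to 24.1% of normalized counts. Across genes, which are not independent replicates, samples correlated with r from 0.921 to 0.982. The leading principal component held 40.2% of the variance and separated the groups, with vehicle samples from -48.6 to -29.5 and oxaliplatin samples from 13.3 to 48.4.

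The comparison of oxaliplatin with vehicle addressed how the drug changed gene expression in the heart, in a study concerned with energy metabolism. In oxaliplatin samples 28 of 31 measured proliferation genes rose, as did 12 of 33 p53 target and DNA damage genes, 14 of 36 extracellular matrix genes and the metallothioneins Mt1 and Mt2. Of fatty acid oxidation genes 13 of 24 fell, as did 6 of 18 genes of ketone and branched-chain amino acid use, 11 of 42 genes of calcium handling and ion channels, and the MHC class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74. In limma, 1966 of 13788 genes passed, 1272 higher and 694 lower, of which 598 and 111 changed at least 2-fold. The groups did not overlap for 1552 of the genes that passed, and for 14.9% of all genes tested, where chance gives 1.59%. Higher genes made up 64.7% of those that passed, and 54.1% after quantile normalization. Genes that passed numbered 1237 without vehicle 2, 1110 without vehicle 3 and 1301 without oxaliplatin 4. The erythroid marker score as a covariate, chosen after seeing the data, gave 1046 genes, and 49 of the 139 genes given by the naming rule that passed in limma did not pass with it. This score was lower in each oxaliplatin sample than in any vehicle sample, except for oxaliplatin 3. The fit can hardly separate score from group, so a call lost with it does not show that blood accounts for the change. Of 47 gene lists tested, 23 passed camera with its preset correlation and 10 passed fry. With an estimated correlation 0 passed camera (lowest adjusted p = 0.552), and 3 had an unadjusted p under 0.05.

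**Figure D1:**
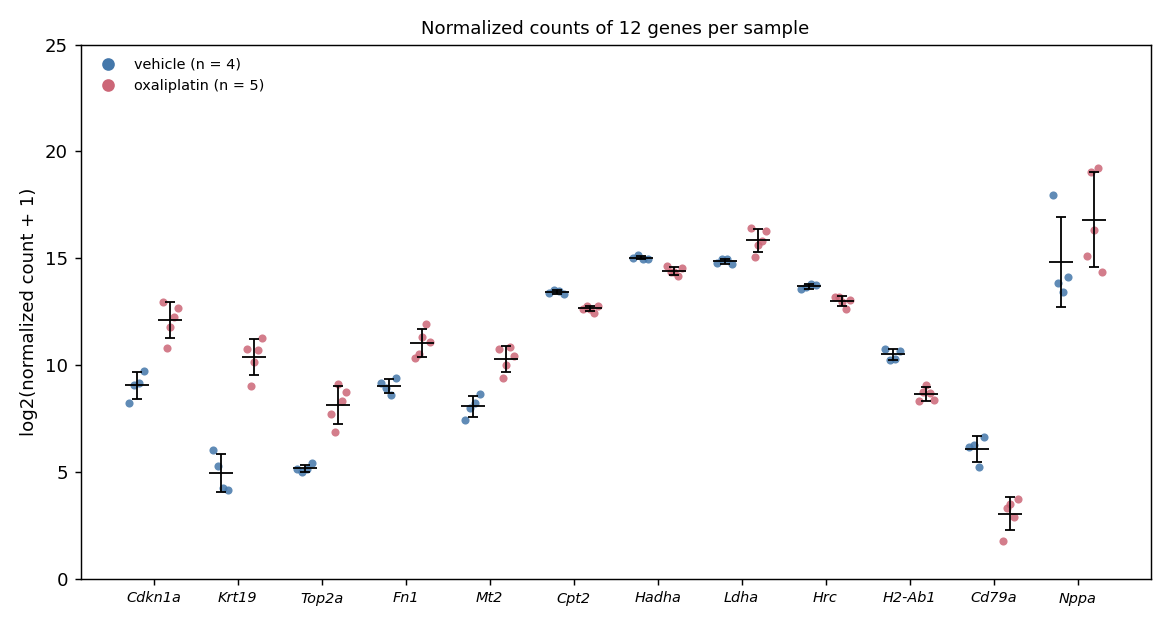
Log2(normalized count + 1) of 12 genes in each sample, for vehicle (n = 4) and oxaliplatin (n = 5); points are samples, horizontal bars are group means and error bars are SD. The groups do not overlap for any of these genes except Nppa.

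Cell division genes rose. Of 31 measured proliferation genes, 28 rose, 0 fell and 3 did not pass, and 29 rose when adjusted over the list alone. Top2a, DNA topoisomerase II alpha, went from 35.4 ± 4.24 to 325 ± 175 normalized counts (SD, n = 4 and n = 5; log2 fold change 2.97, standard error 0.38, limma adjusted p = 9.67e-04). Tpx2, a spindle assembly factor, rose by 3.18 on the log2 scale, Mcm3 of the replicative helicase by 1.32 and thymidylate synthase, Tyms, by 1.10. The list median was 2.76 (camera adjusted p = 2.49e-22; adjusted p = 0.552 with an estimated correlation; fry adjusted p = 0.00978). Among the 10 largest rises named by the rule, 7 were cell division genes with low vehicle means. These means ran from 1.93 normalized counts for Melk to 13.2 for Pimreg. The 7 were Ckap2 (4.45), Pbk (4.30), Gtse1 (4.13), Bub1 (4.12), Melk (4.03), Pimreg (3.93) and Birc5 (3.92). Low vehicle values were not confined to them, as Tnfrsf9, also among the 10, lay between 4.47 and 10.8 in vehicle samples. With voom on estimated reads, chosen after seeing the data, 16 genes of the list rose, and Birc5, Melk and Pimreg did not pass (limma adjusted p = 0.0523, 0.0512 and 0.0949).

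DNA damage genes rose in part. Of 33 measured p53 targets and DNA damage genes, 12 rose, 1 fell and 20 did not pass, and 13 rose and 1 fell when adjusted over the list alone. Cdkn1a, the cell cycle inhibitor p21, lies on chromosome 17 from 29090976 to 29100727 and went from 568 ± 227 to 4934 ± 2417 normalized counts (log2 fold change 3.04, standard error 0.47, limma adjusted p = 0.00480). Psrc1 rose by 3.40, Trp53inp1 by 1.42 and Zmat3 by 1.07, and Gadd45a fell by 1.17. The median of the list was 0.21 (camera adjusted p = 0.00339; adjusted p = 0.560 with an estimated correlation; fry adjusted p = 0.0230). The number that rose was 7 without oxaliplatin 5, and the median was 0.13 without oxaliplatin 1 and 0.36 without the 3 samples of high atrial marker score, where 3 fell.

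Fatty acid oxidation genes, which serve the main ATP supply of adult heart, fell in part. Of 24 measured, 13 fell, 0 rose and 11 did not pass, and 20 fell when adjusted over the list alone. Cpt2, the carnitine palmitoyltransferase of the inner mitochondrial membrane, lies on chromosome 4 from 107903981 to 107923610 and went from 11062 ± 662 to 6484 ± 572 normalized counts (log2 fold change -0.77, standard error 0.11, limma adjusted p = 0.00111). Hadha of the trifunctional protein fell by 0.62, the thioesterase Acot2 by 0.61 and the short-chain dehydrogenase Acads by 0.56. Its median was -0.53 (camera adjusted p = 1.21e-09; adjusted p = 0.552 with an estimated correlation; fry adjusted p = 0.0195). Of 18 measured genes of ketone and branched-chain amino acid use, 6 fell, 0 rose and 12 did not pass, and 10 fell when adjusted over the list alone. Dbt and Bckdha, subunits of the branched-chain ketoacid dehydrogenase, fell by 0.82 and by 0.84, and its phosphatase Ppm1k fell by 0.69 (list median -0.37; camera adjusted p = 1.48e-06; adjusted p = 0.552 with an estimated correlation; fry adjusted p = 0.0195). Cardiomyocyte markers, all 12 with negative log2 fold changes, had a list median of -0.30 and sarcomere genes one of -0.28 in the same samples (camera adjusted p = 0.0108 and 0.00108; adjusted p = 0.626 and 0.560 with an estimated correlation). These lists share genes, and 10 of the 12 cardiomyocyte markers are also in other lists. Erythroid markers had a list median of -2.50. With their score as a covariate 4 fatty acid oxidation genes and 4 ketone and amino acid genes fell. The list medians were then -0.59 and -0.43, and camera passed (adjusted p = 1.55e-09 and 4.98e-07). Without the 3 samples of high atrial marker score the numbers were 2 and 3 at medians of -0.44 and -0.35, with Hadha at an adjusted p of 0.0728, Acot2 at 0.0505 and Acads at 0.0647 (0.0540 with the erythroid covariate). The number of fatty acid oxidation genes that fell was 6 without vehicle 2, 7 without vehicle 3, 8 without oxaliplatin 3 and 8 without oxaliplatin 4, and that of ketone and amino acid genes 11 without oxaliplatin 1. Array weights per sample gave 23 and 15.

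Glycolysis genes rose in part. Of 23 measured genes of glucose uptake and glycolysis, 7 rose, 0 fell and 16 did not pass, and 7 rose when adjusted over the list alone. Ldha, lactate dehydrogenase A, went from 29856 ± 2376 to 62082 ± 21938 normalized counts (log2 fold change 0.98, standard error 0.23, limma adjusted p = 0.0156). Pfkp, a phosphofructokinase, rose by 1.08, the enolase Eno1 by 0.77 and the lactate transporter Slc16a3 by 1.60. The list median was 0.32 (camera adjusted p = 0.0188; adjusted p = 0.727 with an estimated correlation; fry adjusted p = 0.234). Camera did not pass without oxaliplatin 1 (median 0.18, adjusted p = 0.127, 3 genes lower) or with array weights per sample (adjusted p = 0.0509). Nor did it pass with the erythroid score as a covariate (median 0.25, adjusted p = 0.147, 3 genes higher, Ldha at an adjusted p of 0.0810). The number that rose was 4 without vehicle 1 and 4 without vehicle 2, 13 after quantile normalization and 13 with the atrial score as a covariate, where 1 fell, as did 1 without the 3 samples of high atrial marker score. In the same samples fibroblast markers had a list median of 0.66, endothelial markers 0.43 and cardiomyocyte markers -0.30. Whether a change in cell shares accounts for the rise of glycolysis genes was not tested.

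Respiratory chain lists had negative medians and passed camera with its preset correlation, but not with an estimated correlation, nor did they pass fry. No single nuclear-encoded gene of them passed in limma, though some did in other settings. In complex I, 0 of 36 measured genes passed in limma, also when adjusted over the list alone, 6 had an unadjusted p under 0.05 and 35 had negative log2 fold changes, among them Ndufa3 (-0.41). The median of complex I was -0.28 (camera adjusted p = 5.87e-05; adjusted p = 0.695 with an estimated correlation; fry adjusted p = 0.265). In complexes III and IV, 0 of 23 passed, 3 had an unadjusted p under 0.05, and the median was -0.24, with Cox7a1 at -0.60 and Cox6a2 at -0.43 (camera adjusted p = 0.00376; adjusted p = 0.727 with an estimated correlation; fry adjusted p = 0.293). In ATP synthase, 0 of 16 passed, 1 had an unadjusted p under 0.05, and the median was -0.20, with Atp5e at -0.41 and Atp5b at -0.33 (camera adjusted p = 0.0254; adjusted p = 0.727 with an estimated correlation; fry adjusted p = 0.341). These 2 lists also had 0 genes adjusted over the list alone. Of 32 genes of pyruvate dehydrogenase and the TCA cycle, 2 fell and 2 fell adjusted over the list alone, the pyruvate dehydrogenase phosphatases Pdp2 (fell by 1.05) and Pdp1 (fell by 0.63), with a list median of -0.24 (camera adjusted p = 0.00385; adjusted p = 0.695 with an estimated correlation). Of 13 mitochondrially encoded genes, which share reads with nuclear copies and are uncertain, mt-Nd4 fell by 0.49 and 0 fell adjusted over the list alone (median -0.35; camera adjusted p = 0.00410; adjusted p = 0.695 with an estimated correlation). In the same samples the cardiomyocyte markers had a list median of -0.30 (camera adjusted p = 0.0108; adjusted p = 0.626 with an estimated correlation) and the sarcomere genes one of -0.28, and the difference of the respiratory chain lists from these was not tested. Without the 3 samples of high atrial marker score camera passed for none of these 5 lists (medians -0.15, -0.08, -0.09, -0.14 and -0.27, adjusted p = 0.0950, 0.310, 0.498, 0.128 and 0.127). After quantile normalization it passed for none but complex I (medians of the others -0.11, -0.02, -0.08 and -0.10, adjusted p 0.0681, 0.353, 0.280 and 0.254). ATP synthase did not pass camera without vehicle 2 (0.0850), vehicle 3 (0.129), oxaliplatin 2 (0.136), oxaliplatin 3 (0.0742) or oxaliplatin 4 (0.103), nor with the atrial score as a covariate (0.0586). Its median was -0.13 without vehicle 3 and -0.30 without oxaliplatin 1. Genes that fell numbered 5 without oxaliplatin 1 in complex I, 1 without vehicle 4 and 3 without oxaliplatin 1 in complexes III and IV, 1 without vehicle 4 in ATP synthase, 1 without vehicle 1, 1 without vehicle 2, 1 without vehicle 3, 7 without oxaliplatin 1, 1 without oxaliplatin 4 and 1 without oxaliplatin 5 in the TCA list and 0 without vehicle 1, 0 without vehicle 2, 0 without vehicle 3, 10 without vehicle 4, 4 without oxaliplatin 1, 0 without oxaliplatin 2, 0 without oxaliplatin 3, 0 without oxaliplatin 4 and 0 without oxaliplatin 5 among mitochondrially encoded genes. Pdp1 had adjusted p of 0.0694 without vehicle 1, 0.0618 without vehicle 2, 0.0659 without vehicle 3, 0.0570 without oxaliplatin 4 and 0.0541 without oxaliplatin 5. With array weights per sample 20 genes of complex I, 11 of complexes III and IV, 6 of ATP synthase, 15 of the TCA list and 12 mitochondrially encoded genes fell. After quantile normalization 4 complex I genes fell and 1 rose. With it 1 gene of complexes III and IV, 4 of the TCA list and 0 mitochondrially encoded fell. The numbers that fell in these 4 lists were 2, 3, 4 and 2 with the atrial score as a covariate. In the fit with the erythroid score as a covariate 1 TCA gene fell, and genes that did not pass were Pdp1 (0.0825) and mt-Nd4 (0.182), the latter at 0.229 without the 3 samples of high atrial marker score and 0.0652 after quantile normalization.

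Other energy genes changed in both directions. Of 24 regulators of energy metabolism, the coactivator Ppargc1a rose by 0.45 and Ppargc1b fell by 0.58, with 1 higher and 1 lower adjusted over the list alone (median -0.17; camera adjusted p = 0.121). Ppargc1a had an adjusted p of 0.0557 without vehicle 1, where camera passed for the list (0.0417). Pdk4, an inhibitor of pyruvate dehydrogenase, had 2638 ± 209 normalized counts against 4101 ± 1441 and did not pass (limma adjusted p = 0.108). Of 21 genes of fatty acid uptake and storage, 3 rose and 6 fell, and 4 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.468). The lipoprotein receptor Vldlr fell by 0.73, the fat storage protein Fitm1 by 0.75 and Dgat2 of triglyceride synthesis by 0.71. Of 15 phosphagen and nucleotide genes, 2 rose, the creatine kinase Ckb (0.89) and Ucp2 (1.30), and 2 fell, Gatm (-1.13) and Ak3 (-0.37), with 2 and 2 adjusted over the list alone (camera adjusted p = 0.965). The fallers numbered 0 without vehicle 1, 0 without vehicle 2, 0 without vehicle 3 and 1 without oxaliplatin 4. Of 21 sterol and fatty acid synthesis genes, 3 rose and 3 fell, as many as when adjusted over the list alone, with Elovl5 at 0.84, Acly at 0.51 and Acacb at -0.55 (camera adjusted p = 0.472). The synthesis genes that fell numbered 1 without vehicle 2, 1 without vehicle 3, 1 without vehicle 4, 1 without oxaliplatin 3 and 1 without oxaliplatin 4. With the erythroid covariate no regulator passed, 1 uptake gene rose and 3 fell, 1 phosphagen gene rose and 0 fell, and 2 synthesis genes rose and 0 fell. Those named here that lost the call with it were Ppargc1a (0.213), Ppargc1b (0.0884), Fitm1 (0.0528), Ucp2 (0.0646), Gatm (0.203), Ak3 (0.143), Acly (0.0628) and Acacb (0.0778), each with its limma adjusted p. The same held for Ppargc1a (0.0936) and Ak3 (0.172) without the 3 samples of high atrial marker score, and 2 regulators rose with the atrial score as a covariate.

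**Figure D2:**
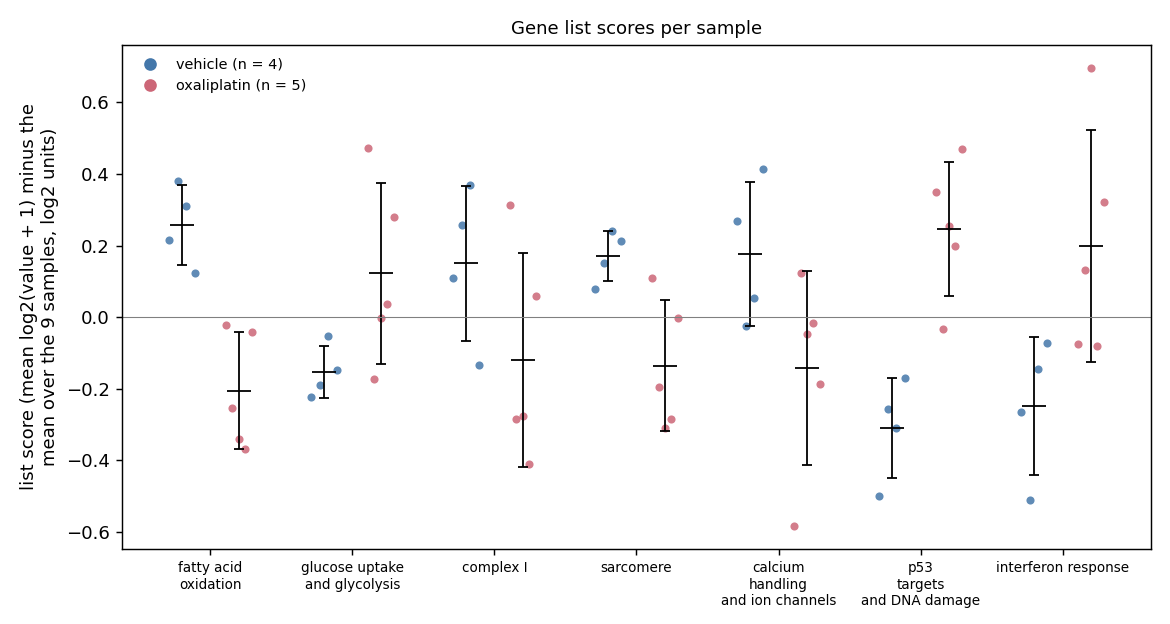
List scores, in log2 units, of 7 gene lists in each sample, for vehicle (n = 4) and oxaliplatin (n = 5); points are samples, horizontal bars are group means and error bars are SD. Fatty acid oxidation scores were lower, and p53 scores higher, in each oxaliplatin sample than in any vehicle sample, and complex I scores overlapped.

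Ion transport and sarcomere genes fell in part. Of 42 measured calcium handling and ion channel genes, 0 rose, 11 fell and 31 did not pass, and 1 rose and 16 fell when adjusted over the list alone. Hrc, a calcium-binding protein of the sarcoplasmic reticulum, went from 13271 ± 1074 to 8260.4 ± 1287 normalized counts (log2 fold change -0.70, standard error 0.14, limma adjusted p = 0.00561). The sodium channel subunit Scn4b fell by 1.45 and the calcium channel subunit Cacna2d1 by 0.82. The median of the list was -0.35 (camera adjusted p = 3.77e-05; adjusted p = 0.552 with an estimated correlation; fry adjusted p = 0.0195). Of 21 sarcomere genes, 0 rose, 4 fell and 17 did not pass, and 6 fell adjusted over the list alone, including Tcap (fell by 0.91) and the myosin heavy chain Myh6 (fell by 0.67). The sarcomere median was -0.28 (camera adjusted p = 0.00108; adjusted p = 0.560 with an estimated correlation; fry adjusted p = 0.0683). Of 12 cardiomyocyte markers, 2 fell, Myh6 and Fabp3 (fell by 0.54), and 2 fell adjusted over the list alone (median -0.30; camera adjusted p = 0.0108; adjusted p = 0.626 with an estimated correlation). Of 6 ventricular markers, 1 rose, Hey2, and 3 fell, including Irx4 (-0.94) and Kcnip2 (-0.85), with 1 and 3 adjusted over the list alone (camera adjusted p = 0.123). Hey2 passed in the fits without vehicle 2 or oxaliplatin 2 and had adjusted p of 0.0916 without vehicle 1, 0.0980 without vehicle 3, 0.0779 without vehicle 4, 0.0563 without oxaliplatin 1, 0.0631 without oxaliplatin 3, 0.0876 without oxaliplatin 4 and 0.0920 without oxaliplatin 5. With the erythroid score as a covariate 3 ion genes and 1 sarcomere gene fell, with list medians of -0.38 and -0.44 and camera passed (adjusted p = 1.25e-04 and 8.70e-05). That covariate ended the calls of all cardiomyocyte and ventricular markers, with limma adjusted p of Myh6 (0.0848), Fabp3 (0.131), Irx4 (0.0527), Kcnip2 (0.0785) and Hey2 (0.167), and those of Scn4b (0.0537) and Cacna2d1 (0.0665). The medians of the cardiomyocyte and ventricular lists were then -0.40 and -0.57 (camera adjusted p = 0.00449 and 0.162). Without the 3 samples of high atrial marker score 9 ion genes and 2 sarcomere genes fell at list medians of -0.49 and -0.24. In that fit 4 ion genes rose, camera did not pass for cardiomyocyte markers (adjusted p = 0.128) and calls were lost for Myh6 (0.0767), Fabp3 (0.302) and Hey2 (0.148). After quantile normalization camera did not pass for the sarcomere or cardiomyocyte lists (medians -0.14 and -0.04, adjusted p = 0.316 and 0.645, 1 gene lower in each, and calls lost for Myh6 (0.227) and Hey2 (0.0795)), nor for the cardiomyocyte list without oxaliplatin 2 (0.0537). Genes that fell numbered 7 without vehicle 3 for ion transport, 2 without vehicle 3 for the sarcomere and 1 without vehicle 1, 1 without vehicle 2, 1 without vehicle 3, 4 without oxaliplatin 1, 1 without oxaliplatin 2, 1 without oxaliplatin 3 and 1 without oxaliplatin 4 for cardiomyocyte markers, and with the atrial score as a covariate 7 sarcomere genes fell and 2 ion genes rose. Array weights per sample gave 8 sarcomere genes and 5 cardiomyocyte markers that fell.

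Heart stress genes rose in part. Of 19 measured fetal and heart stress genes, 5 rose, 1 fell and 13 did not pass, and 6 rose and 1 fell when adjusted over the list alone. Ccn2, a matricellular protein, rose by 2.01, Uchl1 by 1.73 and Fhl1 by 1.02, and the actin-binding Xirp2 fell by 0.76 (list median 0.78; camera adjusted p = 0.0234; adjusted p = 0.560 with an estimated correlation; fry adjusted p = 0.0683). Camera did not pass without vehicle 3 (median 0.24, adjusted p = 0.0546), with array weights per sample (adjusted p = 0.0774) or with the erythroid covariate (median 0.58, adjusted p = 0.207). The number that fell was 2 without vehicle 1 and 2 without the 3 samples of high atrial marker score. Nppb had 5963 ± 1126 normalized counts against 15471 ± 8687 and did not pass (limma adjusted p = 0.0611). Its groups did not overlap (4297 to 6773 against 7078 to 28961), and it passed in 2 of 9 fits without 1 sample. Neither Myh7 (log2 fold change -0.20) nor Nppa (1.99, limma adjusted p = 0.413) passed. Nppa, also an atrial transcript, lay between 10826 and 608521 normalized counts. The atrial marker score was 2.09 in vehicle 1, 2.96 in oxaliplatin 2 and 2.45 in oxaliplatin 4, and between -3.27 and 0.85 in the other samples. Of 12 atrial markers 0 passed in limma, also adjusted over the list alone, and 1 had an unadjusted p under 0.05 (median 0.61; camera adjusted p = 0.311, 0.0342 without vehicle 1 and 0.0199 without oxaliplatin 1). The atrial median was 1.25 without vehicle 1, 0.29 without vehicle 3, 2.01 without oxaliplatin 1, 0.17 without oxaliplatin 2, 0.27 without oxaliplatin 4 and -0.03 without the 3 samples of high atrial marker score. It was 0.98 with the erythroid score as a covariate.

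Extracellular matrix genes rose in part. Of 36 measured matrix and fibrosis genes, 14 rose, 0 fell and 22 did not pass, and 19 rose when adjusted over the list alone. Sparc, a collagen-binding protein, went from 17071 ± 744 to 62014 ± 21709 normalized counts (log2 fold change 1.76, standard error 0.28, limma adjusted p = 0.00266). Fibronectin, Fn1, rose by 2.01, biglycan, Bgn, by 1.33 and Timp3, an inhibitor of metalloproteinases, by 0.96. Over the list the median was 1.06 (camera adjusted p = 1.21e-09; adjusted p = 0.560 with an estimated correlation; fry adjusted p = 0.0683). Of 11 fibroblast markers, 2 rose, Meox1 (1.75) and Dpep1 (0.66), and 3 rose adjusted over the list alone (median 0.66; camera adjusted p = 0.00196; adjusted p = 0.581 with an estimated correlation). Matrix genes that rose numbered 7 without vehicle 2 and 7 without vehicle 3, and fibroblast markers 5 without oxaliplatin 1, and 22 and 6 with array weights per sample. With voom on estimated reads 9 matrix genes rose, and the fibroblast median was 0.43 without the 3 samples of high atrial marker score.

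Epicardial, endothelial and mural markers rose in part. Of 10 measured epicardial and mesothelial markers, 5 rose, 0 fell and 5 did not pass, and 10 rose when adjusted over the list alone. Krt19, a keratin, lies on chromosome 11 from 100140810 to 100148665 and went from 34.5 ± 22.2 to 1506 ± 731 normalized counts (log2 fold change 5.44, standard error 0.52, limma adjusted p = 8.39e-04). The transcription factor Wt1 rose by 2.17 and Rarres2 by 0.98 (list median 2.35; camera adjusted p = 1.49e-07; adjusted p = 0.552 with an estimated correlation; fry adjusted p = 0.0115). Of 12 endothelial markers, 3 rose, 1 fell and 8 did not pass, and 8 rose and 1 fell adjusted over the list alone. The adhesion molecule Pecam1 went from 2321 ± 212 to 5915 ± 1053 normalized counts, Esam rose by 1.07 and the water channel Aqp1 fell by 1.41 (list median 0.43; camera adjusted p = 0.00183; adjusted p = 0.552 with an estimated correlation; fry adjusted p = 0.0195). Of 9 endocardial and lymphatic markers, 3 rose, Lyve1 (1.59), Vwf (1.34) and Pdpn (1.18), and 1 fell, Prox1 (-0.57), with 3 and 2 adjusted over the list alone (camera adjusted p = 0.228). Of 12 smooth muscle and pericyte markers, 3 rose, including Mylk (0.73), and 4 adjusted over the list alone (median 0.59; camera adjusted p = 0.00331; adjusted p = 0.560 with an estimated correlation). Markers that rose numbered 9 without vehicle 1 for the epicardial list, 5 without oxaliplatin 2 for the endothelial list and 1 without vehicle 2, 1 without vehicle 3, 5 without oxaliplatin 2 and 1 without oxaliplatin 3 for the mural list. With the erythroid score as a covariate 3 epicardial markers rose at a list median of 2.24, 1 endocardial or lymphatic marker rose, and calls were lost for Vwf (0.108) and Pdpn (0.0606). Without the 3 samples of high atrial marker score 8 endothelial markers rose and the mural median was 0.33. With the atrial score as a covariate 9 epicardial, 6 endothelial and 5 mural markers rose, and with array weights per sample 6 endothelial and 7 mural markers.

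MHC class II and B cell genes fell in part. H2-Ab1, on chromosome 17 from 34257689 to 34269419, went from 1464 ± 259 to 408 ± 91.9 normalized counts (log2 fold change -1.85, standard error 0.17, limma adjusted p = 4.61e-04), H2-Aa fell by 2.06, H2-Eb1 by 2.04 and the invariant chain Cd74 by 2.11. In the antigen presentation list 3 of 14 rose and 5 fell, and 3 and 5 adjusted over the list alone (camera adjusted p = 0.228). The risers were the MHC class I genes B2m (0.83), H2-D1 (0.72) and H2-K1 (0.55), and the other gene that fell was H2-DMa (-0.80), all 4 named after their values were seen. H2-K1 had adjusted p of 0.0822 without vehicle 2, 0.0782 without vehicle 3, 0.0597 without oxaliplatin 3 and 0.0582 after quantile normalization. The erythroid covariate gave H2-K1 an adjusted p of 0.0919 and H2-DMa one of 0.140, and the fit without the 3 samples of high atrial marker score gave 0.0558 and 0.0961. Of 7 B and plasma cell markers, 1 rose and 4 fell, and 1 and 5 adjusted over the list alone. Cd79a fell by 3.04, the immunoglobulin genes Ighm by 2.39 and Igkc by 1.98, and the riser, named after its values were seen, was Ebf1 (0.46). The list median was -1.98 (camera adjusted p = 0.00376; adjusted p = 0.552 with an estimated correlation; fry adjusted p = 0.0195). Erythroid markers had a list median of -2.50 in the same samples. With their score as a covariate 1 B cell marker fell at a list median of -1.27 and camera did not pass (adjusted p = 0.0575), and H2-Ab1 had a log2 fold change of -1.61 and passed. Calls lost with it were those of Ighm (0.111) and Igkc (0.163), and Igkc had an adjusted p of 0.0506 without the 3 samples of high atrial marker score. The number of B cell markers that rose was 0 without vehicle 1, 0 without vehicle 3, 0 without vehicle 4, 0 without oxaliplatin 1, 0 without oxaliplatin 3, 0 without oxaliplatin 4 and 0 without oxaliplatin 5, 0 with the erythroid covariate and 0 without the 3 samples of high atrial marker score. Of 15 macrophage and monocyte markers, 2 rose, F13a1 (1.05) and Cd68 (1.21), and 2 fell, Timd4 (-3.81) and Cd163 (-1.24), with 2 and 3 adjusted over the list alone (median -0.05; camera adjusted p = 0.604), and the risers numbered 4 without oxaliplatin 1. With the erythroid covariate the calls of Timd4 (limma adjusted p = 0.0694) and Cd163 (0.0895) were lost, though neither changed sign. With it 3 macrophage markers were higher and the list median was 0.52. The median was -0.23 with 4 markers lower with the atrial score as a covariate, and -0.15 after quantile normalization. The largest fall named by the rule was that of the phospholipase Pla2g2d, from 70.7 ± 16.2 to 2.81 ± 3.09 normalized counts (log2 fold change -4.59), and Lilra5 (-3.14), B3galt2 (-2.43) and Cdh23 (-2.17) were among the 10 largest. The last 3 had limma adjusted p of 0.0755, 0.0680 and 0.111 with the erythroid covariate.

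Interferon response genes rose in part. Of 36 measured, 9 rose, 0 fell and 27 did not pass, and 13 rose when adjusted over the list alone. The transcription factor Irf7 rose by 1.51, Xaf1 by 0.72 and the GTPase Irgm1 by 0.54 (list median 0.45; camera adjusted p = 7.09e-06; adjusted p = 0.624 with an estimated correlation; fry adjusted p = 0.122). Of 28 cytokine and chemokine genes, 6 rose and 1 fell, as many as when adjusted over the list alone, including the chemokines Ccl6 (2.20) and Ccl9 (1.32) and the synthase Nos2 (-1.49). Camera did not pass (adjusted p = 0.146), but did in some settings (adjusted p = 0.0329 without vehicle 4, 0.0479 without oxaliplatin 1, 0.0245 with the erythroid score as a covariate and 0.0168 with array weights per sample). Interferon genes that rose numbered 5 without vehicle 1, 3 without vehicle 2, 4 without vehicle 3, 4 without oxaliplatin 3 and 4 without oxaliplatin 5, 5 with limma without trend or robust fitting and 21 with array weights per sample. Cytokine genes that rose numbered 2 without vehicle 2, 2 without vehicle 3 and 3 without oxaliplatin 4, and those that fell 2 without oxaliplatin 2 and 2 without the 3 samples of high atrial marker score. The chemokine receptor Ackr2 rose by 3.88 and Tnfrsf9 by 4.85, the latter with limma adjusted p = 0.398 with voom on estimated reads. Tnfrsf9 had low vehicle values, between 4.47 and 10.8 normalized counts.

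**Figure D3:**
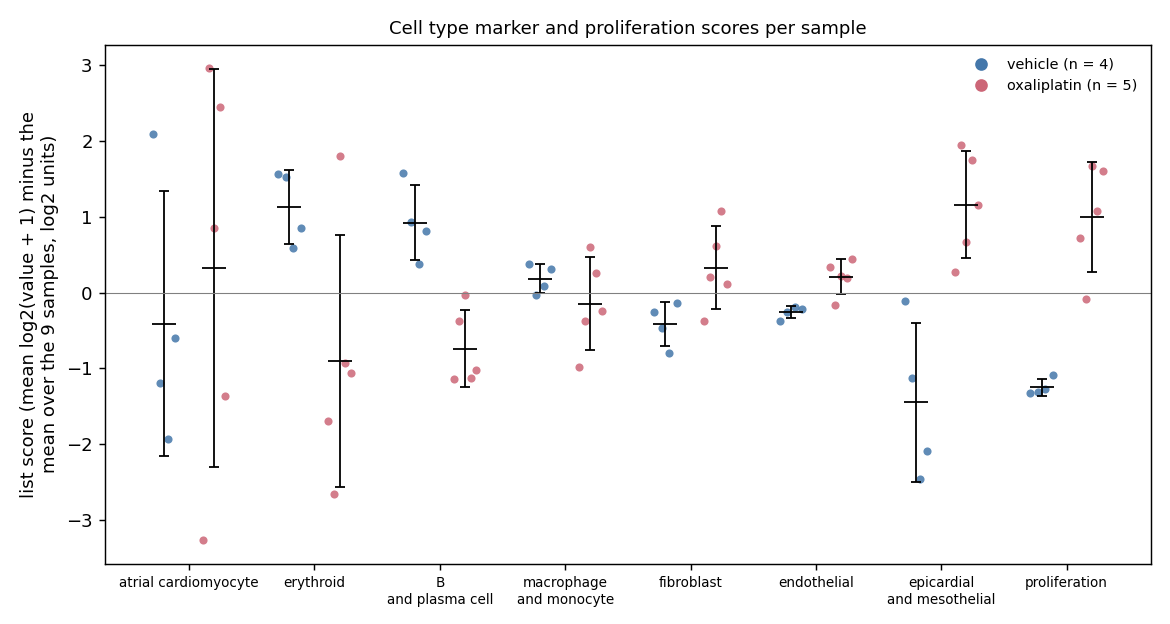
List scores, in log2 units, of 7 sets of cell type markers and the proliferation list in each sample, for vehicle (n = 4) and oxaliplatin (n = 5); points are samples, horizontal bars are group means and error bars are SD. Proliferation scores were higher, and B cell scores lower, in each oxaliplatin sample than in any vehicle sample, and atrial and erythroid scores overlapped.

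Blood cell markers varied between samples. The erythroid score lay between 0.58 and 1.56 in vehicle samples, between -2.65 and -0.92 in 4 oxaliplatin samples, and was 1.80 in oxaliplatin 3. Of 10 erythroid markers 0 passed in limma, 8 had an unadjusted p under 0.05 and 6 fell adjusted over the list alone, with Hba-a2 at -3.27 (median -2.50; camera adjusted p = 2.33e-04; adjusted p = 0.581 with an estimated correlation; fry adjusted p = 0.147). The number that fell was 8 without oxaliplatin 3, 4 fell with limma without trend or robust fitting, and the median was -1.65 without the 3 samples of high atrial marker score. Of 6 neutrophil and 5 platelet markers 0 passed, also adjusted over the list alone, and 1 and 0 had an unadjusted p under 0.05, with Mmp9 at -1.67 and Itga2b at -1.14. Camera gave adjusted p = 0.0650 and 0.389, and passed for neutrophil markers without vehicle 2 (0.0216), vehicle 3 (0.0175), oxaliplatin 3 (0.0171) or oxaliplatin 4 (0.0439) and after quantile normalization (0.0413, 1 marker lower). For platelet markers it passed with the atrial score as a covariate (adjusted p = 0.0251, 2 markers lower).

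Metal-binding and stress genes changed in part. The metallothioneins Mt2 and Mt1, which bind zinc and other metals, rose by 2.20 and 1.30, Mt1 from 8847 ± 2210.0 to 22529 ± 7778 normalized counts (limma adjusted p = 0.00923). Of 21 metal handling and platinum transport genes, 4 rose and 1 fell, Abcc1 (-0.50), as many as when adjusted over the list alone. The median was 0.21, 0.12 without vehicle 1 and 0.10 without the 3 samples of high atrial marker score (camera adjusted p = 0.125; adjusted p = 0.552 with an estimated correlation; fry adjusted p = 0.00978). Of 27 NRF2 and antioxidant genes, 3 rose and 2 fell, and 5 and 4 adjusted over the list alone, with heme oxygenase, Hmox1, at 1.72 and Gpx1 at 0.56 (camera adjusted p = 0.965). Of 23 genes of the integrated stress response and unfolded proteins, 4 rose and 5 rose adjusted over the list alone, including asparagine synthetase, Asns (1.07), and Mthfd2 (1.24) (camera adjusted p = 0.367; adjusted p = 0.627 with an estimated correlation; fry adjusted p = 0.0344). Of 15 heat shock genes, 3 fell and 3 fell adjusted over the list alone, including the mitochondrial chaperonin Hspd1 (fell by 0.62), with a median of -0.31 (camera adjusted p = 0.00385; adjusted p = 0.581 with an estimated correlation). Metal genes that rose numbered 2 without vehicle 3 and those that fell 0 without vehicle 2, 0 without vehicle 3, 0 without vehicle 4, 0 without oxaliplatin 1, 2 without oxaliplatin 2, 0 without oxaliplatin 4 and 0 without oxaliplatin 5, antioxidant genes that fell 0 without vehicle 2, 0 without vehicle 3, 1 without vehicle 4, 4 without oxaliplatin 1, 1 without oxaliplatin 2, 1 without oxaliplatin 3 and 1 without oxaliplatin 4, stress response genes that rose 2 without vehicle 3 and 2 without vehicle 4, and heat shock genes that fell 1 without vehicle 3 and 6 without oxaliplatin 1. With the erythroid covariate 2 metal genes rose, calls were lost for Mt1 (0.0853) and Abcc1 (0.247), 0 antioxidant genes fell and the heat shock median was -0.55. With the atrial score as a covariate 3 metal genes fell and 6 antioxidant genes rose. After quantile normalization 4 antioxidant genes fell, and without the 3 samples of high atrial marker score 0 antioxidant genes and 1 stress response gene fell. Array weights per sample gave 5 antioxidant and 6 heat shock genes that fell.

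The remaining lists had few changes. Of 18 clock genes 3 fell, including Dbp (-0.92), and 1 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.108), and the number that fell was 1 without vehicle 1, 1 without vehicle 2, 1 without vehicle 3, 1 without vehicle 4, 6 without oxaliplatin 2, 1 without oxaliplatin 4 and 1 without oxaliplatin 5 and 1 with the erythroid score as a covariate. Camera passed for clock genes without the 3 samples of high atrial marker score (adjusted p = 0.0383), where 1 rose and 6 fell, and 1 rose and 6 fell with the atrial score as a covariate. With array weights per sample 5 clock genes and 4 ribosomal protein genes fell and 3 atrophy and autophagy genes rose. Of 21 glucocorticoid and fasting genes 3 rose and 3 fell, and 3 and 4 adjusted over the list alone, including Fkbp5 (1.77), Angptl4 (1.74) and Pik3ip1 (-0.73) (camera adjusted p = 0.934). In that list 1 rose with the erythroid score as a covariate, Angptl4 at an adjusted p of 0.0545. Of 22 atrophy, autophagy and mitophagy genes 1 rose and 2 fell, the mitophagy kinase Pink1 (-0.76) and the ubiquitin ligase Fbxo32 (-0.59), and 2 and 2 adjusted over the list alone (camera adjusted p = 0.907). The number that rose was 0 without vehicle 1, 0 without vehicle 2, 0 without vehicle 3, 0 without vehicle 4, 0 without oxaliplatin 1, 2 without oxaliplatin 2, 0 without oxaliplatin 4 and 0 without oxaliplatin 5, 0 with the erythroid and 4 with the atrial score as a covariate, 4 after quantile normalization and 3 without the 3 samples of high atrial marker score. Of 50 ribosomal protein genes 1 rose, Rpl3 (0.62; adjusted p = 0.0562 without vehicle 3 and 0.144 with the erythroid covariate), and 0 adjusted over the list alone (camera adjusted p = 0.231, 1.40e-05 without vehicle 4, 0.0314 without oxaliplatin 1 and 1.15e-04 with array weights per sample). Of 23 immediate early genes 0 passed in limma, also adjusted over the list alone, and 4 had an unadjusted p under 0.05, with Maff at 1.46 and Jun at -1.07 (camera adjusted p = 0.227). Without vehicle 1, 9 of them fell (camera adjusted p = 7.41e-06), and without the 3 samples of high atrial marker score, of which vehicle 1 is 1, 12 fell (median -1.27 against -0.60; camera adjusted p = 6.69e-08). White adipocyte, brown adipocyte and Schwann markers had 1 of 7 (Fabp4, 0.96), 1 of 6 (Ppargc1a) and 2 of 9 (Pmp22, 1.05, and Ncam1, 1.05) higher, with 1, 1 and 2 adjusted over the list alone (camera adjusted p = 0.0810, 0.583 and 0.934). White adipocyte markers, with a median of 1.33 and of -0.05 without the 3 samples of high atrial marker score, passed camera without oxaliplatin 1 (adjusted p = 9.13e-04), after quantile normalization (0.0380) and with array weights per sample (0.0319). Fabp4 had adjusted p of 0.0505 without vehicle 1, 0.0532 without vehicle 2 and 0.0588 without vehicle 4, and Ncam1 of 0.0711 without vehicle 2 and 0.0741 without vehicle 3, and both lost the call with the erythroid covariate (0.0791 and 0.133). Of 7 skeletal muscle markers 0 passed in limma, also adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.725). Lists with under 5 measured members had no test. Of their genes Satb1 of the thymocyte list fell by 0.72 and Hopx of the lung list by 0.99. Of the 3 measured genes of the lung list 2 had positive log2 fold changes. Cd4 of the T cell list (0.52), Tg of the thyroid list (0.24) and the 4 sex-linked genes did not pass.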

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

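Tests chosen only after the result was seen were the B cell median for proliferation, the comparison with sarcomere genes and the erythroid covariate for fatty acid oxidation, the macrophage median for MHC class II, and the fry splits, and the atrial and erythroid covariates were themselves added after seeing the data.

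A sample stood far from the others of its group in 19 of 426 groups of values, where chance gives about 5%, or 21.3. Each value is the gap to the nearest other sample divided by the range of the group. Vehicle 4 accounted for 9 of them. It was far above the other vehicle samples for Vldlr (0.937), Ccn2 (0.881) and Scn4b (0.844), and far below them for Gatm (0.92), Gpx1 (0.877), Irgm1 (0.955), Angptl4 (0.832), Nppb (0.853) and the ribosomal protein score (0.893). Vehicle 1 was far below for the immediate early gene score (0.876) and far above for Nppa (0.838). Oxaliplatin 2 was far below the other oxaliplatin samples for Tnfrsf9 (0.714), Gpx1 (0.773), Sparc (0.733) and Elovl5 (0.776), and far above for the brown adipocyte score (0.863). Oxaliplatin 1 was far below for Cacna2d1 (0.761) and far above for Csf3r (0.739), and oxaliplatin 4 was far above for Timp3 (0.739).

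Proliferation genes were higher in oxaliplatin samples. With a pseudocount of 5, 28 of them rose, which argues against low counts alone, although voom on estimated reads gave 16 (list median 2.84). With the atrial score as a covariate 28 rose, which argues against atrial tissue. B and plasma cell markers had a median log2 fold change of -1.98, which argues against B cells carried along. For T cells, 1 of the 12 listed T and NK cell markers was measured, Cd4 at 0.52. Each deposited gene reached at least 40.6 in some sample, so the other markers may have been low in all samples. Why they are absent is not given, so T cells stay open. An effect of the drug on division of heart cells stays open as a hypothesis, untested.

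Fatty acid oxidation genes were lower in oxaliplatin samples. With the atrial score as a covariate 13 of the 13 that fell passed, which argues against a trend with the atrial score as the whole cause. Without the 3 samples of high atrial score 2 passed at a median of -0.48, with a median standard error of 0.18 against 0.14. Fewer samples alone could lower that count, so it does not decide on atrial tissue. With the erythroid score as a covariate the median of the 13 genes was -0.65, against -0.59 without it, and 4 passed, while the median standard error went from 0.14 to 0.19. The erythroid score was lower in each oxaliplatin sample than in any vehicle sample, except for oxaliplatin 3 (1.80). This fit therefore rests mainly on oxaliplatin 3 and cannot decide whether less blood accounts for the fall. A smaller share of cardiomyocytes cannot be told apart from a fall within them: the score minus the sarcomere score differed by -0.156 log2 units between groups (exact permutation p = 0.0476), but, while the difference stayed negative (-0.214 to -0.108), p was under 0.05 in 1 of 9 repeats without 1 sample, that without vehicle 4 (exact p = 0.0179, the smallest that fit allows), and reached 0.143 without oxaliplatin 1.

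MHC class II genes were lower in oxaliplatin samples. With the atrial score as a covariate 4 of Cd74, H2-Aa, H2-Ab1 and H2-Eb1 passed, which argues against atrial tissue as the whole cause. With the erythroid score as a covariate 4 passed, Cd74 at -1.64 against -2.11. That fit rests mainly on oxaliplatin 3, the only oxaliplatin sample whose erythroid score was not below those of vehicle, so less blood is not excluded. The macrophage list had a median of -0.0473, and from -0.39 without oxaliplatin 3 to 0.24 without oxaliplatin 1, changing sign, and 0.52 with the erythroid covariate. Its members moved both ways (SD 1.21), so this argues only against a loss of all macrophages alike by as much as the median of the 4 genes (-2.05), while a smaller loss, or one of those with Timd4 and Cd163 (adjusted p = 0.0694 and 0.0895 with the erythroid covariate), stays open. Fewer B cells stay open too, since the B and plasma cell list had a median of -1.98.

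Of 126 splits of the samples into 4 and 5, 100 were drawn. Chance can be excluded for the number of genes, as 1 split, the real one, gave as many as 1966 and the highest other gave 1787. That other split set oxaliplatin 1, 3, 4 and 5 against the rest, so it differs from the real one only by oxaliplatin 2. Of the splits other than the real one, 92 gave 0 genes. Chance cannot be excluded for the number of lists by camera, as 28 splits gave at least 23 and the highest other gave 32. The median over the splits other than the real one was 17 lists by camera. By fry, chosen for this after the camera splits were seen, 3 splits gave at least 10 lists and the highest other gave 12. A split of vehicle 2, vehicle 3, oxaliplatin 1 and oxaliplatin 5 against the rest also gave 10. The share lies under 0.05, but fry was tried after camera and a mixed split reached as many lists, so chance is not called excluded.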

How the results depend on the processing

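The covariates, the removal of 3 samples and voom were chosen after seeing the data. Over 24 settings, 0 of the 139 genes given by the naming rule that passed changed sign. Every setting reused the samples that gave these calls, so a constant sign was likely beforehand. In the settings that tested these genes, 76 passed throughout and 63 were lost in at least 1. Of those lost, 49 were lost with the erythroid covariate and 31 without 1 sample or another. A gene below the filter of a setting was not tested there. Against 1966 genes in limma (1272 higher, 694 lower), array weights gave 3541 (1975 higher, 1566 lower), and the cause was not tested. The atrial covariate gave 1043 lower genes, and the erythroid covariate 1046 genes (793 higher, 253 lower), and the cause was not tested. The erythroid score separated the groups except for oxaliplatin 3, so lost calls there may reflect that overlap of score and group. Without 1 sample, genes ranged from 1110 (without vehicle 3) to 2388 (without oxaliplatin 2), higher genes from 789 to 1508, lower genes from 321 to 880 and lists from 21 to 27, and the cause was not tested. Lists that passed camera numbered 23, 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 10 by fry, which tests another question. Other settings gave between 1405 and 2666 genes at the same threshold. Quantile normalization gave 2132 (1154 higher, 978 lower).

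With the replicate block, 1405 genes and 26 lists passed, without oxaliplatin 5, which has no partner. Samples of the same number did not deviate together (r from -0.27 to 0.25 across genes), so the numbers were not taken to pair the samples. The edgeR and DESeq2 alternatives were not run, because whole reads were not recovered. The simulated recovery at 1.5-fold, which may be understated for these data, limits what can be said of small changes.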

Other observations

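The gene families, and the tests of S phase background and of genes with higher vehicle means, were chosen only after results were seen.

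Of 20 families grouped by symbol and tested together, 13 passed camera with its preset correlation and 0 with an estimated correlation. Of the 13, 4 picked after their values were seen are given. Families that did not pass included kinesins (7 of 25 higher and 2 lower; camera adjusted p = 0.0920), integrins (2 and 2 of 23; 0.486), solute carriers (27 and 16 of 219; 0.486) and potassium channels (3 and 6 of 34; 0.284). Of 15 tubulins 9 rose and 0 fell (median log2 fold change 0.78; camera adjusted p = 7.35e-06; adjusted p = 0.137 with an estimated correlation). Of 10 annexins 6 rose (median 0.73; camera adjusted p = 2.67e-04; adjusted p = 0.222 with an estimated correlation), and of 10 septins 6 rose, but 3 without vehicle 2 and 1 without vehicle 3 (median 0.47; camera adjusted p = 2.67e-04; adjusted p = 0.143 with an estimated correlation). Of 81 mitochondrial ribosomal protein genes 2 fell and 0 rose (median -0.21; camera adjusted p = 1.29e-05; adjusted p = 0.507 with an estimated correlation). Those that fell numbered 1 without vehicle 1, 0 without vehicle 2, 0 without vehicle 3, 10 without oxaliplatin 1, 1 without oxaliplatin 2, 0 without oxaliplatin 3, 0 without oxaliplatin 4 and 5 without oxaliplatin 5, and 9 after quantile normalization. With the erythroid covariate 4 annexins, 6 tubulins and 3 septins rose and 1 mitochondrial ribosomal protein gene fell. The atrial covariate gave 10 tubulins higher and 1 lower, and 4 mitochondrial ribosomal protein genes lower. Without the 3 samples of high atrial score 4 septins rose, 0 mitochondrial ribosomal protein genes fell and the median of the latter was -0.13. The medians of these 4 families had the same sign with TMM and quantile scaling. Median-of-ratios scaling could hardly alter them, since its factors were equal over the samples.

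A hypothesis was that oxaliplatin samples may hold cells stopped in G2 or M phase. Of 53 G2 and M phase genes 42 rose (median 2.68), and of 39 S phase genes 15 rose (median 0.48). The difference of their scores was 1.41 higher in oxaliplatin samples (exact permutation p = 0.0159, two-sided, smallest possible 0.00794). The median rise of G2 and M phase genes in normalized counts was 3.13 times that of S phase genes. This ratio has no spread and compares different genes, so a higher background of S phase genes in cells that do not divide stays open. Among genes with a vehicle mean of at least 50, 19 of G2 and M phase and 27 of S phase, the scores differed by 0.08 (exact permutation p = 0.278), and a background of S phase genes would give such a small difference, so both explanations stay open.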
